A study of Mus musculus with 8 samples.

How the data were processed

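RNA of mouse primary myotubes was measured by RNA-seq in 8 libraries, 2 per group, in 4 groups: control and MPC EV at 12 h and at 24 h. Per the labels' protocols, EVs were isolated with a polymer-based method, libraries were not strand-specific, and paired ends were sequenced on an Illumina NovaSeq instrument. The authors deposited 1 table of FPKM values, with 1 column per library and 35275 genes. Per the submitters' processing notes, HISAT2, DESeq2 (version given as 2) and the mm10 build were used, with no role stated for each. The counting tool, the annotation release and any filters are not given in the sources used here. FPKM divides by gene length and by the library's total, so a few abundant transcripts or a change in their share moves all other values of a library. No scaling between libraries is stated.

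Ensembl gene IDs were matched to symbols and GRCm38 coordinates in GENCODE vM21, whose release may differ from the authors' annotation. A symbol was found for 34490 IDs and none for 785. Of the 10981 tested genes, 36 had no symbol. No column lacked a sample, and no 2 columns held identical values. Depth was read from the steps of low values: in 5477 of 21185 genes (25.9%) all 8 values were whole multiples of what 1 fragment is worth, within a tolerance of 0.02. Among tested genes this held for 1002 (9.12%), so counts were not recovered for most genes and no count test was run. The depth came to 18.7 and 19.9 M fragments (M for mega) in control 12 h replicates 1 and 2, 17.3 and 18.3 in MPC EV 12 h, 19.7 and 20.2 in control 24 h and 16.3 and 18.0 in MPC EV 24 h. These are estimates from the step sizes, and counting error is smallest for abundant and long genes.

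Genes with a mean of at least 1 FPKM over the 8 libraries were tested on log2(FPKM + 0.5) with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The EV effects at 12 h and 24 h and their difference came from a fit of the 4 groups with 4 residual degrees of freedom. The EV effect over both times and the time effect came from a fit with both terms and 5 residual degrees of freedom. All groups shared 1 estimate of spread per gene, because 2 libraries against 2 leave few degrees of freedom. The 34 gene lists cover muscle structure and regulation, matrix, inflammation, metabolism, stress and growth, RNA classes and markers of other cell types, and 28 had at least 5 tested members. These were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 prepared tables and figures.

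The groups, tests, gene lists, most alternatives and the rule for named genes were set before the data were examined. That rule takes, for each of the 4 comparisons, the 10 genes with the largest rise and the 10 with the largest fall among those that passed, had both libraries of a group above both of the other, a mean of at least 2 FPKM and a symbol that is not a predicted gene, clone, pseudogene or mitochondrial name. It adds up to 4 members of each list with the smallest adjusted p, Rrbp1 in every comparison, and the 5 genes with the smallest p for the difference of the effects. Some results under this rule are not reported.

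The steps were tested on simulated data, drawn for each gene around its mean over the libraries with its residual SD, with 200 genes changed. At a log2 change of 0.5, 1 and 2, the share of changed genes recovered was 31.3%, 70.1% and 93.9% at 12 h, 29.9%, 71.6% and 90.9% at 24 h, 59.7%, 92.5% and 98.5% over both times, 59.7%, 92.5% and 93.9% for time and 10.4%, 52.2% and 84.8% for the difference of the effects. Between 4 and 8 of 10981 genes were false calls. With 1 list raised by a log2 of 1, camera called that list and no other of the 28. The simulated genes were independent of each other and had the same spread in all libraries. In the data the estimated correlation within the sarcomere list was 0.558 in the fit of the 4 groups. The simulation therefore does not show how often camera calls lists falsely here.

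Alternatives were other pseudocounts (0.1 and 1), other filters on low values (means of at least 0.1 or 5 FPKM, and none), median-ratio scaling, quantile normalization, no variance trend, the replicate number as a term, each library left out, and fits to the libraries of 1 time. Array weights and a correction for GC content and transcript length were added after the data were seen. In the fit of the 4 groups the weights were equal for both libraries of a group, so they cannot single out 1 of them. The correction regressed each library's deviation from the mean of the 8 libraries on GC content and log2 length of the longest coding transcript, or of the longest transcript where none is coding, and 99.7% of tested genes had these values. That regression held an intercept, so the correction also removed each library's mean shift. DESeq2 was not used here because it needs counts.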

Results

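Multinucleated muscle cells formed in culture (myotubes) were grown from primary myogenic progenitor cells (MPCs) of C57BL6/J mice and exposed to extracellular vesicles (EVs), the small membrane particles that cells release, collected from MPCs. Control myotubes received EVs prepared from growth medium. No untreated myotubes are among the samples, so a rise with MPC EVs cannot be told from a fall with the control preparation. RNA was sequenced after 12 h and 24 h, with 2 libraries per treatment and time and 8 libraries in all. The study asked how MPC EVs change gene expression in myotubes. Values are FPKM (fragments divided by gene length and by the library's mapped total), given as mean ± SD with n = 2 libraries per group. The step size of low values put the depth at 16.3 to 20.2 M fragments (M for mega) per library. Fragment numbers could be recovered for 1002 tested genes (9.12%). These had a median of 159 to 198 fragments depending on the library, which may not hold for the other tested genes. The labels do not say that the 2 libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. All fold changes are differences on the log2(FPKM + 0.5) scale, which understates the change of low genes, and all adjusted p-values for genes are from limma with Benjamini-Hochberg adjustment.

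The libraries of 3 groups were close to their partners, with correlations of log2 values across genes of 0.992 to 0.996. Control 12 h replicate 2 correlated with its partner at 0.947. In that library, 243 transcripts that were both long and low in GC content had a median of -1.73 relative to the mean of the other libraries on the log2 scale, while 1187 short, GC-rich transcripts had a median of 0.22. Transcripts encoded in mitochondria took 1.56% of its FPKM, against 2.09% to 4.81% in the other 7 libraries. Results without this library, chosen after seeing the data, are therefore given for each comparison.

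**Figure D1:**
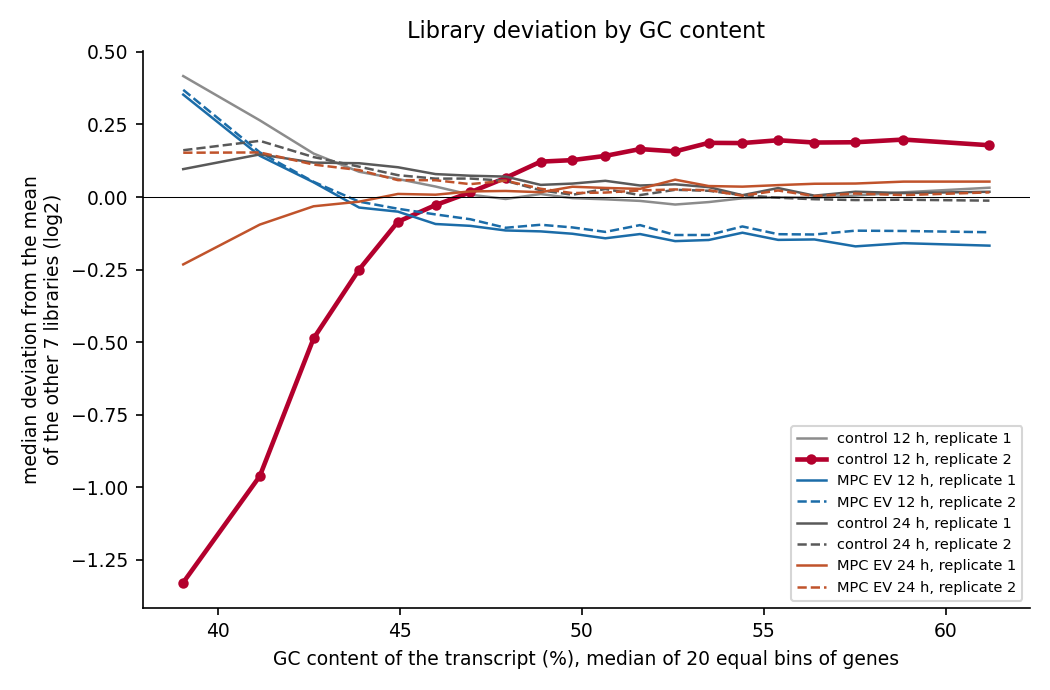
Median deviation of each library from the mean of the other 7 libraries (log2 scale) against transcript GC content (%), in 20 bins of equal gene number; each line is 1 library. Control 12 h replicate 2 lies lowest for GC-poor transcripts and highest for GC-rich ones.

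After 12 h, transcripts of the contractile apparatus were higher in myotubes given MPC EVs. Actn2, the alpha-actinin of the Z disc (ENSMUSG00000052374, chromosome 13, 12269426 to 12340760 in GRCm38/mm10), went from 40.5 ± 6.0 to 127.0 ± 0.133 FPKM, a log2 fold change of 1.64 ± 0.12 (SE, adjusted p = 0.00245). Myh3, the embryonic myosin heavy chain (ENSMUSG00000020908, chromosome 11, 67078300 to 67102291), rose from 436.2 ± 38.1 to 1232.1 ± 2.21 FPKM (adjusted p = 0.00245). The largest increase with small spread was that of Lmcd1, a LIM-domain transcriptional cofactor (ENSMUSG00000057604, chromosome 6, 112273758 to 112330425), from 2.05 ± 0.0219 to 19.9 ± 2.0 FPKM (log2 fold change 2.99 ± 0.20, adjusted p = 0.00245). The largest fall was that of Colq, which encodes the collagen tail of acetylcholinesterase (ENSMUSG00000057606, chromosome 14, 31523082 to 31591343), from 10.4 ± 1.28 to 0.776 ± 0.156 FPKM (log2 fold change -3.09 ± 0.21, adjusted p = 0.00245).

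Of 32 tested sarcomere genes, 14 rose at 12 h, none fell and 18 did not pass (16 higher and 1 lower when adjusted over the list alone). The slow myosin heavy chain Myh7 reached a log2 fold change of 1.62 ± 0.12 and the titin cap Tcap one of 1.64 ± 0.11. The list's median was 0.30, or 0.42 relative to all genes. Of its members, 15, 22 and 26 were higher with median-ratio scaling, quantile normalization and GC and length correction, 7 with array weights, and 5 without MPC EV 12 h replicate 1 or replicate 2. Without control 12 h replicate 1, 15 were higher and 2 lower. It was called by camera (adjusted p = 9.01e-11, and adjusted p = 0.726 with an estimated correlation). The rises of Ttn, Neb and Mef2c, with log2 fold changes of 1.99, 2.03 and 2.07, rested in part on control 12 h replicate 2: without it they were 1.21, 1.17 and 1.18 and still passed. In the same comparison the marker lists of other cells had medians of -0.29 for progenitors, -0.30 for fibroblasts and -0.26 for pericytes and smooth muscle, against -0.12 for all genes. Camera called none of them in the main test (adjusted p = 0.744, 0.594 and 0.937). After GC and length correction the medians were -0.20, -0.05 and -0.03. With cell cycle genes included, 58 markers had a median of -0.37, with 3 higher and 24 lower, and 16 of the lower ones were cell cycle genes. Of 19 genes of excitation-contraction coupling and the neuromuscular junction, 4 rose and none fell (8 and 1 adjusted over the list alone), among them the sodium channel Scn4a at 1.53 ± 0.15 and the calcium channel Cacna1s at 0.60 ± 0.13 (camera adjusted p = 0.00061, and adjusted p = 0.726 with an estimated correlation). With median-ratio scaling, quantile normalization and GC and length correction 9, 9 and 8 were higher. Of 24 genes of cholesterol synthesis, 6 rose and none fell (the same counts adjusted over the list alone; 9, 6 and 11 higher under the same 3 alternatives). Examples were Hmgcs1 at 0.55 ± 0.09 and Dhcr7 at 0.56 ± 0.10 (camera adjusted p = 1.03e-06, and adjusted p = 0.688 with an estimated correlation).

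Genes of the NF-kB and acute inflammatory response were lower at 12 h. Of 17 tested genes, 11 fell and none rose (13 and 0 adjusted over the list alone), with a median log2 fold change of -0.68, or -0.56 relative to all genes (camera adjusted p = 6.27e-06, and adjusted p = 0.688 with an estimated correlation). Several are feedback inhibitors or subunits of the pathway and are themselves induced by it. Nfkbia, the inhibitor IkB-alpha (ENSMUSG00000021025, chromosome 12, 55489410 to 55492647), went from 33.1 ± 1.32 to 8.51 ± 1.32 FPKM, and Nfkbie, the inhibitor IkB-epsilon, from 20.5 ± 1.22 to 3.67 ± 0.375 FPKM. Bcl3 and the subunit gene Nfkb2 had log2 fold changes of -2.55 ± 0.20 and -1.24 ± 0.07. Of 7 tested chemokines and cytokines, 4 fell (6 adjusted over the list alone), including Ccl2 at -1.81 ± 0.23 and Lif at -1.11 ± 0.16 (camera adjusted p = 0.00897, and adjusted p = 0.726 with an estimated correlation). The matrix metalloproteinase Mmp9 (ENSMUSG00000017737, chromosome 2, 164940780 to 164955850) fell from 5.50 ± 0.144 to 0.502 ± 0.0921 FPKM. In the TGF-beta list 11 of 21 genes fell and 1 rose (also 11 and 1 adjusted over the list alone): Ltbp2, which encodes a protein of elastic fibres, fell, while the ligand gene Tgfb3 rose by 0.81 ± 0.07. Camera did not call that list (adjusted p = 0.198, and adjusted p = 0.813 with an estimated correlation).

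Cell cycle genes were lower as a group at 12 h: 16 of 32 fell and none rose (22 and 0 adjusted over the list alone), with a median of -0.43, or -0.31 relative to all genes (camera adjusted p = 4.5e-05, and adjusted p = 0.688 with an estimated correlation). The ribonucleotide reductase subunit Rrm2 fell by 1.28 and Mcm6, a subunit of the replicative helicase, fell by 0.66 on the log2 scale. The count of fallen members was 13 without control 12 h replicate 2, 11 with median-ratio scaling, 10 with quantile normalization and 6 after GC and length correction. Of 30 ribosomal protein genes, 15 fell (29 adjusted over the list alone; camera adjusted p = 4.1e-06, and adjusted p = 0.813 with an estimated correlation), but 1 fell without control 12 h replicate 2 and 0 with median-ratio scaling, where the list's median was still -0.22. The mitochondrially encoded mRNAs moved with the same library: 0 of 12 passed (0 adjusted over the list alone), their median was 0.49 (camera adjusted p = 0.0264, and adjusted p = 0.813 with an estimated correlation), and without control 12 h replicate 2 it was -0.13 (adjusted p = 0.808). In the glycolysis and hypoxia list 2 of 24 genes rose and 1 fell (9, 10 and 11 rose and 1 fell with median-ratio scaling, quantile normalization and GC and length correction; adjusted over the list alone as in the main test; camera adjusted p = 0.013, and adjusted p = 0.813 with an estimated correlation). Without control 12 h replicate 1 that call ended (adjusted p = 0.587), as did the call of excitation-contraction and neuromuscular junction genes (adjusted p = 0.0599).

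Left without control 12 h replicate 2, the data had 16 sarcomere genes higher at 12 h, 8 of excitation-contraction and the neuromuscular junction, 12 of cholesterol synthesis (19 adjusted over the list alone) and 7 of glycolysis and hypoxia, with 1 lower. NF-kB had 11 lower and chemokines 3. Camera then also called myogenic regulation and fusion (9 higher and 3 lower, against 5 and 5 in the main test, adjusted p = 0.0407), the unfolded protein response (2 higher, adjusted p = 0.0151) and immediate early genes (4 higher and 3 lower, adjusted p = 0.0237). With an estimated correlation these had adjusted p = 0.446, 0.723 and 0.647.

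Over all 10981 tested genes, 479 were higher and 1566 lower at 12 h, and 92 and 96 of these changed over 2-fold. Without control 12 h replicate 2 the counts were 631 and 1145. The median gene changed by -0.12 and by 0.01 with median-ratio scaling, a shift over 0.1 that bears on small changes of this comparison. List medians are therefore also given relative to all genes. The higher share of the calls was 23.4%, against 57.3% with median-ratio scaling, 40.4% with quantile normalization and 58.2% after GC and length correction. The number of calls rested on the spread being estimated over all 8 libraries: fitted to the 4 libraries at 12 h alone, 2 genes were higher and 9 lower, and leaving out each library in turn gave from 70 higher and 142 lower (without MPC EV 12 h replicate 1) to 2183 higher and 3488 lower (without control 12 h replicate 1).

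**Figure D2:**
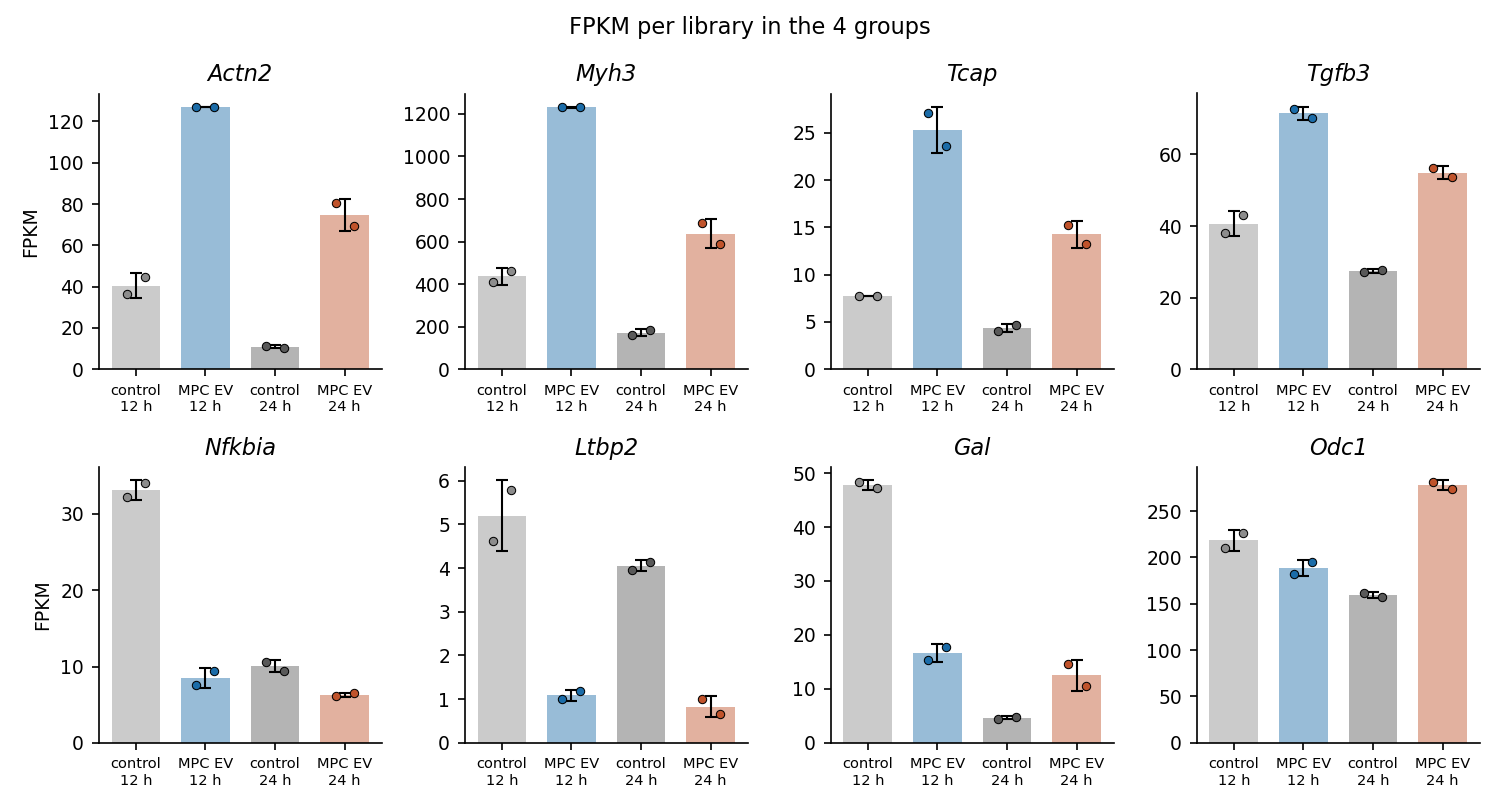
FPKM of 8 genes in the 4 groups; dots are single libraries, bars are means and error bars are SD (n = 2 libraries per group). Actn2, Myh3, Tcap and Tgfb3 are higher with MPC EVs at both times, Nfkbia and Ltbp2 are lower at both, and Gal and Odc1 lie below control at 12 h and above it at 24 h (the 12 h difference of Odc1 did not pass).

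After 24 h the same contractile transcripts stood among the largest increases. Actn2 was 11.0 ± 0.586 FPKM in control and 74.8 ± 7.81 FPKM with MPC EVs (log2 fold change 2.71 ± 0.12, adjusted p = 0.00196). Myh3 was 172.2 ± 14.7 and 637.4 ± 68.7 FPKM (1.88 ± 0.11, adjusted p = 0.00205), and the perinatal myosin Myh8 was 29.6 ± 2.99 and 123.6 ± 27.3 FPKM (2.03 ± 0.16, adjusted p = 0.00311). Of 32 sarcomere genes 15 rose, none fell and 17 did not pass (26 higher and 0 lower adjusted over the list alone). With the replicate number as a term within each time, 0 passed. Without control 24 h replicate 1 or 2, 4 or 6 were higher, and without MPC EV 24 h replicate 1 or 2, 5 or 7. Without MPC EV 12 h replicate 1 or 2 there were 9, without control 12 h replicate 1 or 2 there were 22, and 22, 21 and 25 with quantile normalization, GC and length correction and array weights. The median was 0.50, and camera called the list (adjusted p = 8.43e-24, and adjusted p = 0.658 with an estimated correlation). Not all members moved: Des, Actn3 and Myom2, named after their values were seen, had log2 fold changes of -0.01, -0.11 and 0.01 (adjusted p = 0.98, 0.816 and 0.986). The myosin heavy chain genes are closely related, so fragments may be shared between them in the authors' counting. Outside the list, Ankrd2, a stretch-responsive ankyrin repeat gene of muscle, rose from 7.32 ± 0.930 to 35.8 ± 5.23 FPKM (2.21 ± 0.13), Lmcd1 by 2.81 ± 0.20 and Thbd, which encodes thrombomodulin, by 1.92 ± 0.16.

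Part of the glycolysis and hypoxia list and of the excitation-contraction and neuromuscular junction list also passed at 24 h. Of 24 glycolysis and hypoxia genes 5 rose and none fell (10 and 0 adjusted over the list alone; median 0.23; camera adjusted p = 1.04e-07, and adjusted p = 0.658 with an estimated correlation), including Pfkm, the muscle phosphofructokinase, at 0.62 ± 0.10 and Aldoa at 0.52 ± 0.09. Of 19 excitation-contraction and neuromuscular junction genes 3 rose (5 adjusted over the list alone), among them the calcium-binding Casq2 at 0.62 ± 0.11 (camera adjusted p = 0.00104, and adjusted p = 0.759 with an estimated correlation). In the list of 22 immediate early genes 6 rose and 2 fell (7 and 3 adjusted over the list alone; camera adjusted p = 0.0268, and adjusted p = 0.759 with an estimated correlation). The members that rose included Dusp6 at 1.37 ± 0.10 and Dusp5 at 1.26 ± 0.11, phosphatases that act on ERK kinases, the nuclear receptor Nr4a1 at 1.45 ± 0.10 and Fosl1 at 0.95 ± 0.10, while Egr1 and Fos, named after their values were seen, had -0.09 and 0.29 (adjusted p = 0.925 and 0.673). Plau and Plaur, the urokinase protease and its receptor, rose by 1.15 ± 0.10 and 0.63 ± 0.07. The matrix gene Tnc rose by 1.19 ± 0.15, and Col12a1 and Col6a1 fell by 1.54 and 1.11.

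The falls at 24 h were led by Mmp9, from 2.82 ± 0.238 to 0.135 ± 0.0816 FPKM (-2.39 ± 0.15, adjusted p = 0.00212), and Islr, a gene of stromal cells (ENSMUSG00000037206, chromosome 9, 58156268 to 58204306), from 13.5 ± 0.711 to 2.33 ± 0.137 FPKM (-2.31 ± 0.15, adjusted p = 0.00212). Ltbp2 (ENSMUSG00000002020, chromosome 12, 84783212 to 84876532) went from 4.05 ± 0.125 to 0.826 ± 0.239 FPKM. In the TGF-beta list 4 of 21 genes fell and 1 rose (6 and 1 adjusted over the list alone; camera adjusted p = 0.046, and adjusted p = 0.82 with an estimated correlation). Of the NF-kB list 3 of 17 fell, Nfkbie, Nfkbia and Nfkb2 (2 higher and 7 lower adjusted over the list alone; camera adjusted p = 0.0393, and adjusted p = 0.818 with an estimated correlation). That call was lost without control 12 h replicate 1 or 2, control 24 h replicate 1 or MPC EV 24 h replicate 1 (adjusted p = 0.121, 0.122, 0.111 and 0.0959), and the TGF-beta call without control 24 h replicate 2 or MPC EV 24 h replicate 2 (adjusted p = 0.0996 and 0.114). Of 21 other settings, these included, the NF-kB call was kept in 12 and the TGF-beta call in 13. No interferon response gene passed over all genes, and 3 of 8 were lower adjusted over the list alone (camera adjusted p = 0.013, and adjusted p = 0.658 with an estimated correlation). Likewise none passed among 30 ribosomal protein genes (median -0.13, 0 adjusted over the list alone, camera adjusted p = 0.000315, and adjusted p = 0.838 with an estimated correlation). None passed among 27 oxidative phosphorylation genes (median 0.08, 0 adjusted over the list alone, adjusted p = 0.0268, and adjusted p = 0.838 with an estimated correlation), 7 histone genes (median 0.32, 3 higher adjusted over the list alone, adjusted p = 0.0268, and adjusted p = 0.658 with an estimated correlation) or 7 chemokines (median 0.18, 1 higher adjusted over the list alone, adjusted p = 0.0379, and adjusted p = 0.759 with an estimated correlation). Leaving out control 24 h replicate 2 or MPC EV 24 h replicate 1 also ended the calls of oxidative phosphorylation (adjusted p = 0.195 and 0.492) and chemokines (0.18 and 0.112). Without MPC EV 24 h replicate 2 the calls of histones, immediate early genes and ribosomal proteins ended (0.136, 0.136 and 0.0629), and that of histones also without control 24 h replicate 2 (0.167).

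At 24 h, 7 excitation-contraction and neuromuscular junction genes and 8 of glycolysis and hypoxia were higher without control 12 h replicate 2. Of the TGF-beta list 6 were lower, of NF-kB 4 with 1 higher, and of the interferon response 3, while 2 chemokines, 2 histones and 1 oxidative phosphorylation gene were higher. Camera then also called myogenic regulation and fusion (7 higher and 2 lower, adjusted p = 0.0479), cholesterol synthesis (1 higher, adjusted p = 0.0365) and atrophy and proteolysis (2 lower, adjusted p = 0.0417). With an estimated correlation each had adjusted p = 0.688.

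In all, 287 genes were higher and 105 lower at 24 h, with 76 and 29 over 2-fold. With the replicate number as a term within each time, 0 were higher and 0 lower. The counts were 584 and 323 without control 12 h replicate 2, and 491 and 272 when only the 4 libraries at 24 h were fitted. Leaving out each library in turn gave from 23 higher and 4 lower (without control 24 h replicate 1) to 602 and 356 (without control 12 h replicate 1).

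**Figure D3:**
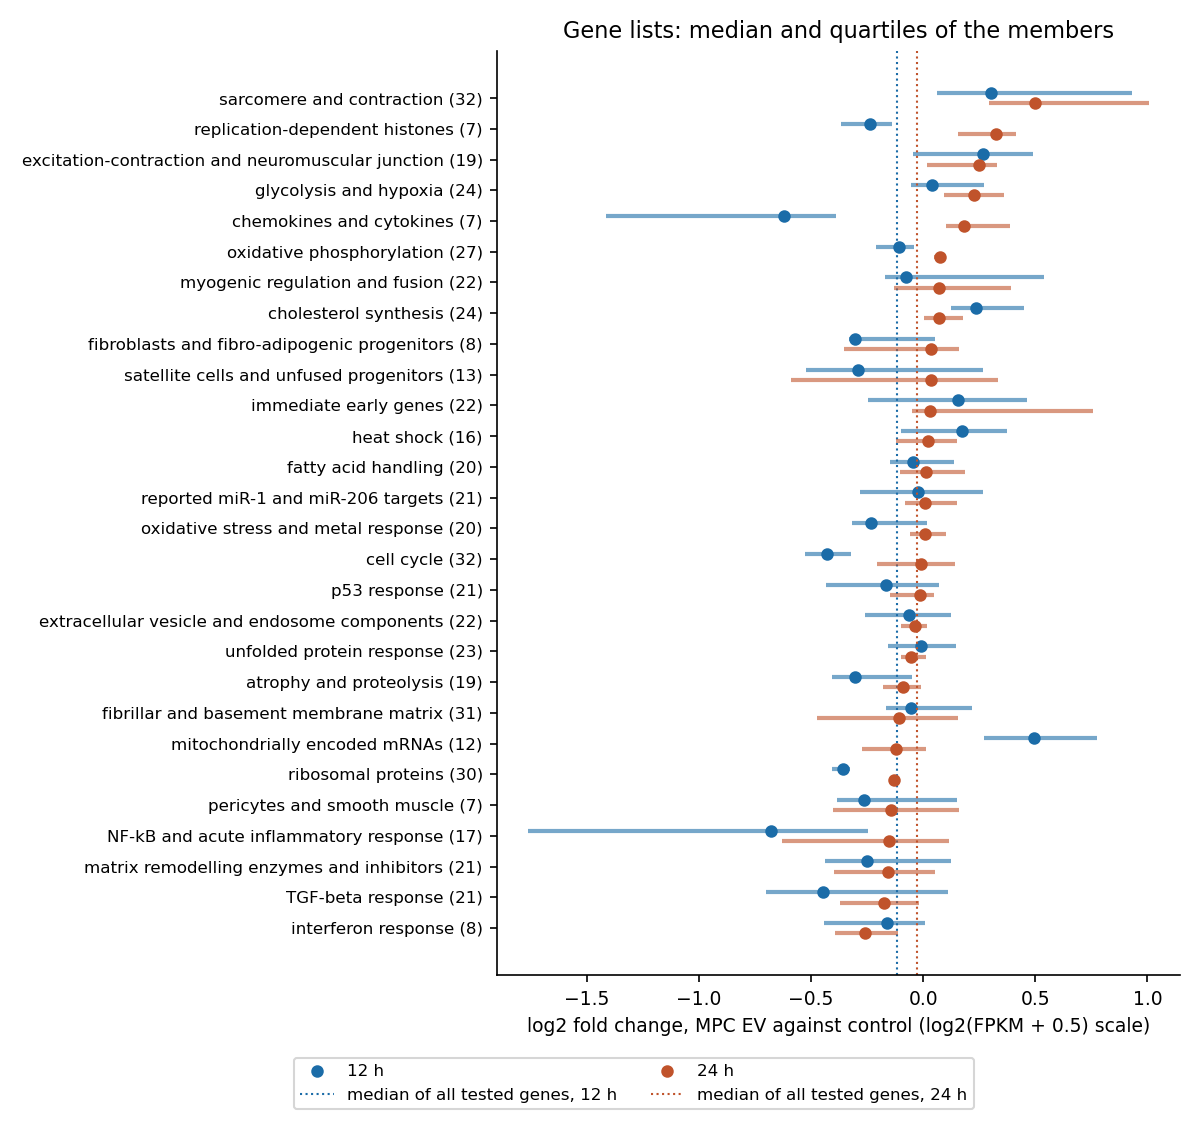
Median log2 fold change (dots) and quartiles (bars) of the tested members of each gene list, MPC EV against control at 12 h and 24 h on the log2(FPKM + 0.5) scale, with the number of tested members in parentheses; dotted lines are the medians of all tested genes. The sarcomere list stands highest at 24 h, with a median of 0.50, and the NF-kB list lowest at 12 h, with -0.68.

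Over both times, with time as a term in the fit, Lmcd1, Actn2 and Tcap were higher with MPC EVs. Their log2 fold changes were 2.90 ± 0.14, 2.18 ± 0.21 and 1.62 ± 0.08 (limma adjusted p = 0.000165, 0.00199 and 0.000165). Each was higher in 4 of 4 MPC EV libraries than in the controls of their time. Gzme and Mcpt8, both on chromosome 14 (56117626 to 56120625 and 56082166 to 56085273), rose by 2.35 ± 0.27 and 2.02 ± 0.20. Fragments from related genes cannot be excluded. Tmem176b and Tmem176a on chromosome 6 (48833818 to 48841496 and 48840919 to 48847071) fell by 2.03 and 1.96. These genes overlap, and the library does not keep the strand, so fragments in the overlap cannot be assigned to either. Mymx, which encodes the fusion peptide myomixer, fell by 1.15 (SE 0.06, adjusted p = 0.000165), from 75.7 ± 3.24 to 34.5 ± 3.54 FPKM at 24 h. In the list of myogenic regulation and fusion 6 of 22 genes rose and 4 fell (7 and 4 adjusted over the list alone). The members that rose include Cav3 at 0.90 ± 0.12 and Klhl41 at 0.57 ± 0.07 (list median -0.00 and mean 0.16; camera adjusted p = 0.109, and adjusted p = 0.793 with an estimated correlation). Rrbp1, a ribosome-binding protein of the endoplasmic reticulum named by a rule set in advance (ENSMUSG00000027422, chromosome 2, 143947395 to 144011263), was at 22.7 ± 1.59 and 20.1 ± 2.31 FPKM at 12 h and 23.6 ± 0.497 and 22.3 ± 0.885 FPKM at 24 h. Its log2 fold change over both times was -0.13 ± 0.07 (adjusted p = 0.296).

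By list over both times, 15 of 32 sarcomere genes rose and none fell (19 and 0 adjusted over the list alone; camera adjusted p = 9.23e-20, and adjusted p = 0.636 with an estimated correlation). Excitation-contraction and neuromuscular junction genes had 7 of 19 higher (9 higher and 1 lower adjusted over the list alone; adjusted p = 3.52e-05), glycolysis and hypoxia 7 of 24 (7 adjusted over the list alone; adjusted p = 9.59e-06) and cholesterol synthesis 3 of 24 (3 adjusted over the list alone; adjusted p = 9.59e-06). Each of these 3 had adjusted p = 0.636 with an estimated correlation. With median-ratio scaling, quantile normalization and GC and length correction, glycolysis and hypoxia had 9, 12 and 12 higher. Under the same alternatives excitation-contraction and neuromuscular junction genes had 9, 9 and 8 higher and cholesterol synthesis 4, 3 and 2. Immediate early genes had 6 higher and 3 lower (7 and 3 adjusted over the list alone; adjusted p = 0.0321, and adjusted p = 0.793 with an estimated correlation). Ribosomal proteins had 2 of 30 lower (28 adjusted over the list alone; adjusted p = 1.59e-07, and adjusted p = 0.793 with an estimated correlation) and NF-kB genes 7 of 17 (9 adjusted over the list alone; adjusted p = 0.00306, and adjusted p = 0.793 with an estimated correlation). Cell cycle genes had 3 of 32 lower (3 adjusted over the list alone; adjusted p = 0.0247, and adjusted p = 0.831 with an estimated correlation). Under the 3 alternatives above, 1, 4 and 3 ribosomal protein genes, 7, 7 and 8 NF-kB genes and 1, 1 and 3 cell cycle genes were lower. Of 21 other settings, the calls over both times of immediate early genes were kept in 16, of cell cycle genes in 17 and of NF-kB genes in 19. The cell cycle call ended without control 12 h replicate 1 or MPC EV 12 h replicate 1 (adjusted p = 0.109 and 0.0662), and that of immediate early genes without control 12 h replicate 1 or MPC EV 24 h replicate 2 (0.0704 and 0.064). The sarcomere list had 24 higher without control 12 h replicate 2, and 21, 23 and 27 with median-ratio scaling, quantile normalization and GC and length correction. Without that library excitation-contraction and neuromuscular junction genes had 9 higher, glycolysis 8 and cholesterol synthesis 4, and ribosomal proteins had 6 lower, NF-kB 7 and cell cycle 3. Camera then also called myogenic regulation and fusion (7 higher and 4 lower, adjusted p = 0.0179) and oxidative phosphorylation (0 higher and 0 lower, adjusted p = 0.0345). With an estimated correlation these had adjusted p = 0.388 and 0.888.

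Camera compares a list with all other genes. With an estimated correlation between genes it kept 0 of the 9, 11, 8 and 13 calls at 12 h, at 24 h, over both times and for time. Fry, which tests whether a list's genes move on balance in 1 direction without comparing them to other genes, called 15, 3, 8 and 16 lists. Over both times 461 genes were higher and 477 lower, and 656 and 669 without control 12 h replicate 2. The higher share was 49.1%, against 65.6% with median-ratio scaling and 59.9% after GC and length correction. Leaving out each of the other 7 libraries in turn gave 240 to 318 higher and 158 to 251 lower.

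**Figure D4:**
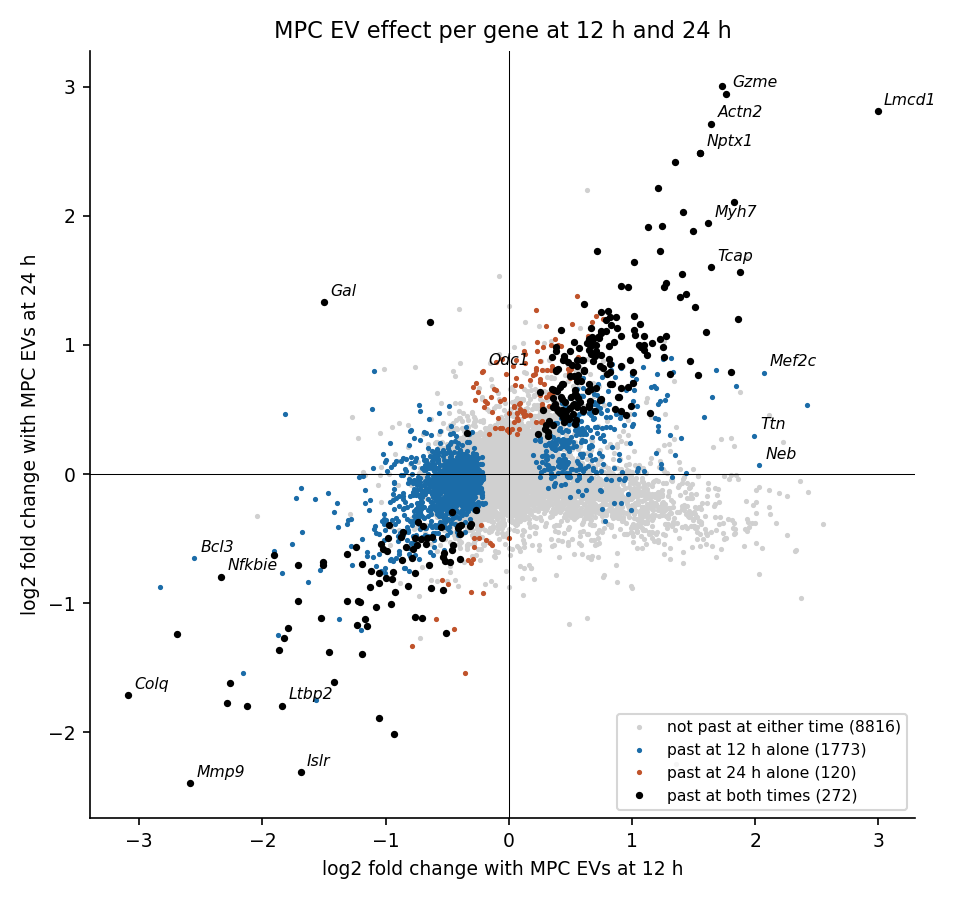
Log2 fold change with MPC EVs at 24 h against that at 12 h for each tested gene on the log2(FPKM + 0.5) scale; colours show genes past an adjusted p of 0.05 in limma at 12 h, at 24 h, at both or at neither. Genes past at both times have the same sign except for 3, Gal, Mcrip2 and Lce1g, of which the last 2 were named after their values were seen.

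The effects at the 2 times were then compared. Of the genes higher at 24 h, 183 were also higher at 12 h, against 12.5 in independent lists of the same sizes, and 86 were lower at both times, against 15.0. The lists are not independent, because both effects share each gene's estimate of spread. A gene with a small spread is more easily called at both times. Of the 392 genes called at 24 h, 92.6% had the same sign at 12 h. Across all 10981 genes, which are not independent replicates, the effects correlated at r = 0.23 (Spearman rho 0.15). Other assignments of treatment within each time gave r from -0.59 to 0.38, so this value is not outside them. Over the 2165 genes called at either time r was 0.76, in genes selected for their effects. The r over all genes was 0.55 without control 12 h replicate 2, 0.04 without control 12 h replicate 1, 0.03 without MPC EV 24 h replicate 2 and 0.42 without MPC EV 24 h replicate 1.

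A difference between the 2 effects was tested gene by gene. The smallest p belonged to Gal, which encodes the neuropeptide galanin (ENSMUSG00000024907, chromosome 19, 3409915 to 3414544). It fell with MPC EVs from 47.8 ± 0.877 to 16.6 ± 1.72 FPKM at 12 h and rose from 4.61 ± 0.270 to 12.5 ± 2.88 FPKM at 24 h. Odc1, the ornithine decarboxylase of polyamine synthesis (ENSMUSG00000011179, chromosome 12, 17544794 to 17551505), was at 218.5 ± 11.6 and 188.4 ± 8.72 FPKM at 12 h and rose from 159.6 ± 3.43 to 278.0 ± 5.32 FPKM at 24 h. The differences of the effects were 2.83 ± 0.22 and 1.01 ± 0.09 on the log2 scale and did not pass (limma adjusted p = 0.0756 for both). The other genes with the smallest p, 1700012B09Rik, Smco4 and Nfkbie, had differences of 1.61, 1.07 and 1.54 (adjusted p = 0.0756, 0.0985 and 0.0985). Limma called 0 of 10981 genes, with 2014 at an unadjusted p under 0.05. It called 3 (Gal, Odc1 and 1700012B09Rik) without control 12 h replicate 2 (adjusted p = 0.0255, 0.0255 and 0.0416), 3668 without control 12 h replicate 1 and 1 without MPC EV 24 h replicate 2. Effects called at only 1 of the times are therefore not shown to differ between the times.

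In the fit with both terms, more genes passed for time than for MPC EVs. The secreted muscle protein gene C1qtnf3 (ENSMUSG00000058914, chromosome 15, 10952332 to 10980150) fell from 181.1 ± 4.36 to 51.9 ± 0.105 FPKM in controls and from 211.5 ± 12.5 to 55.6 ± 0.721 FPKM with MPC EVs (log2 fold change -1.86 ± 0.05, adjusted p = 1.23e-05). Frmpd1 fell by 2.51 on the log2 scale. Car6, a secreted carbonic anhydrase (ENSMUSG00000028972, chromosome 4, 150187015 to 150201332), rose by 2.52 ± 0.11, Ostn, a muscle-secreted peptide gene, by 2.44 ± 0.13 and Avil by 2.52 ± 0.16. Sarcomere genes fell with time, 20 of 32 against 2 that rose (23 and 2 adjusted over the list alone; camera adjusted p = 3.92e-12, and adjusted p = 0.452 with an estimated correlation). Myh3, Myh7 and Actc1 had log2 fold changes of -1.15 ± 0.10, -1.22 ± 0.10 and -1.03 ± 0.09. Of 22 myogenic regulation and fusion genes 12 fell and 1 rose (12 and 1 adjusted over the list alone; adjusted p = 3.16e-07, and adjusted p = 0.452 with an estimated correlation), with Mymx at -1.35 ± 0.06.

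Of the stress lists, camera called those of the unfolded protein response and of oxidative and metal stress for time, but not heat shock (2 of 16 higher and 1 lower, 2 and 0 adjusted over the list alone, adjusted p = 0.319). In the unfolded protein response 13 of 23 genes rose and none fell (15 and 0 adjusted over the list alone; camera adjusted p = 3.16e-07, and adjusted p = 0.452 with an estimated correlation). The chaperone gene Hspa5 went from 838.3 ± 49.5 to 1574.7 ± 76.2 FPKM in controls, and Ddit3 and Ppp1r15a rose by 0.91 ± 0.07 and 1.36 ± 0.09. In the oxidative and metal stress list 12 of 20 rose (12 higher and 1 lower adjusted over the list alone; adjusted p = 2.44e-05, and adjusted p = 0.452 with an estimated correlation), with the metallothionein gene Mt2 at 1.07 ± 0.07. Of 32 cell cycle genes 14 rose (15 adjusted over the list alone; adjusted p = 0.000752, and adjusted p = 0.5 with an estimated correlation), such as Ccnb1 at 1.68 ± 0.08. Ribosomal protein genes had 13 of 30 higher (21 adjusted over the list alone; adjusted p = 1.28e-05, and adjusted p = 0.544 with an estimated correlation). Without control 12 h replicate 2 all 30 were higher. The p53 list had 8 of 21 higher and 1 lower (10 and 1 adjusted over the list alone; adjusted p = 0.0026, and adjusted p = 0.452 with an estimated correlation). The atrophy and proteolysis list had 9 of 19 higher and 2 lower (11 and 3 adjusted over the list alone; adjusted p = 0.0198, and adjusted p = 0.5 with an estimated correlation). Of that list the cathepsin Ctsl rose by 1.00 ± 0.04 and the ubiquitin ligase gene Trim63 fell by 1.09. Reported miR-1 and miR-206 targets had 7 of 21 higher and 1 lower (9 and 1 adjusted over the list alone; adjusted p = 0.00893, and adjusted p = 0.452 with an estimated correlation).

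Also lower with time were the TGF-beta list with 7 of 21 genes (7 adjusted over the list alone; camera adjusted p = 1.04e-05, and adjusted p = 0.452 with an estimated correlation), cholesterol synthesis with 8 of 24 (1 higher and 12 lower adjusted over the list alone; adjusted p = 7.06e-05, and adjusted p = 0.5 with an estimated correlation) and NF-kB with 5 of 17 (5 adjusted over the list alone; adjusted p = 0.000378, and adjusted p = 0.5 with an estimated correlation). Excitation-contraction and neuromuscular junction genes had 7 of 19 lower and 2 higher (8 and 3 adjusted over the list alone; adjusted p = 0.00256, and adjusted p = 0.5 with an estimated correlation). Of 12 mitochondrially encoded mRNAs 1 was lower (0 adjusted over the list alone, median -0.28, adjusted p = 0.0587). Of 7 pericyte and smooth muscle genes 4 were lower and 2 higher (the same adjusted over the list alone, median -0.33, adjusted p = 0.0702).

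The unfolded protein response had 20 higher with time without control 12 h replicate 2, oxidative and metal stress 14, p53 13 with 1 lower, cell cycle 17 with 2 lower, atrophy 11 with 4 lower and the reported miR-1 and miR-206 targets 11 with 1 lower. The sarcomere list had 20 lower and 2 higher, myogenic regulation 15 and 3, TGF-beta 9 and 0, cholesterol synthesis 10 and 1, NF-kB 5 and 1, and excitation-contraction and neuromuscular junction genes 9 and 3. Camera then also called the mitochondrially encoded mRNAs (9 of 12 lower, median -0.62, adjusted p = 1.78e-05, and adjusted p = 0.372 with an estimated correlation).

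Of all genes 1485 were higher and 1008 lower at 24 h, with 96 and 148 over 2-fold, and 2523 and 1644 without control 12 h replicate 2. The higher share was 59.6%, against 48.4% with median-ratio scaling. Time and the age of the cultures after the EVs were added are the same variable here.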

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

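The tests of GC and length bias in control 12 h replicate 2, of the 12 h counts without that library and of fewer unfused cells were chosen only after the result was seen, as was the GC and length correction itself, and the transcript used for GC content and length was changed after the trend was first seen.

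The gap of control 12 h replicate 2 to the nearest library, divided by the range of the 8 libraries, was 0.714 for the SD of its deviation, 0.622 for the share of the deviation explained by GC content and length and 0.636 for the median of long, GC-poor transcripts, each above Dixon's critical value for 8 libraries, which chance passes in about 1 in 20 groups. It was below that value for its correlation with GC content (0.435) and length (0.315), its mitochondrial share (0.165), its genes above 0 (0.312) and its sum of FPKM (0.386). GC content and transcript length explained 50.6% of its deviation and at most 20.6% in any other library, which is consistent with a bias in that library. A wrong label was argued against only after correction: its correlation was then 0.974 with its partner and 0.968 with the next library of another group. The margin was 0.00657 against an SD of 0.00303 among the 6 others, and this comparison with the SD was added after the first values were seen. As deposited the order was reversed, with 0.947 for its partner and 0.957 for MPC EV 24 h replicate 1. The case against a wrong label therefore rests on the correction. Where such a bias arose (RNA quality, library preparation) was not tested, and no biological explanation was tested.

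Of the genes called at 12 h, 23.4% were higher with MPC EVs. Control 12 h replicate 2 alone was argued against as the whole cause, since without it the share was 35.5%. The share was 58.2% after GC and length correction and 57.3% with median-ratio scaling, so either may account for the excess of lower genes. The correction also removes each library's mean shift, and the median gene at 12 h moved from -0.12 to -0.03 with it. The 58.2% therefore cannot tell GC and length bias apart from scaling. A broad fall of small size stays open as well, because scaling by the median and the correction each remove one. The count of NF-kB genes lower at 12 h was 11 in the main test and with each.

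Sarcomere genes were higher at 24 h, with a median log2 fold change of 0.50. GC and length bias and scaling were argued against, since the median was 0.47 after GC and length correction, with 21 of 32 genes called, and 0.52 with median-ratio scaling. Fewer unfused or other cells in the treated wells would raise all sarcomere genes alike if those cells held none of these transcripts, which was not tested. Of the sarcomere genes, 53.1% (17 of 32, 5 below and 12 above) lay over 2 SE from the list's median. This test replaced a first one after the value of the first was seen. The first was the median of 58 markers of progenitors, other cells and dividing cells. That median was -0.00 (quartiles -0.30 to 0.18) at 24 h and -0.37 (quartiles -0.52 to -0.03) at 12 h. The replacement excludes a uniform rise only as the whole cause at 24 h. Fewer other cells stay open for part of that rise, and for all of it if they hold these transcripts unequally. They also stay open for the rise at 12 h. An effect of MPC EVs on some sarcomere genes is a hypothesis that stays open, and the labels give no other difference between the groups that was tested.

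Other genes were noted because both MPC EV libraries lay below both controls at 12 h and above both at 24 h. The difference between the effects was tested for each and did not pass. Of the 5 genes with the smallest p, Gal had a difference of 2.83, 1700012B09Rik of 1.61 and Odc1 of 1.01 (adjusted p = 0.0756), and Smco4 of 1.07 (0.0985). Ccl2 had 2.28, Vcam1 0.89, Mcm6 0.86, Mcm4 0.71 and Pcna 0.48 (adjusted p = 0.0985). Cd34 had 0.96, and the histone genes Hist1h2bc 0.69 and Hist1h1c 0.62 (adjusted p = 0.114). Hist1h4i had 1.04 (0.13), Cacng1 0.47 (0.136), Hk1 0.41 (0.14), Gja1 0.44 (0.146) and Ftl1 0.36 (0.157).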

How the results depend on the processing

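Array weights and the GC and length correction, alone or with the replicate block, were chosen after seeing the data. The counts of genes moved more than their direction. Named genes that passed were followed through 21 other settings, wherever the gene was tested. None reversed, but calls were lost. In every one of these settings 34 of 105 passed at 12 h, 0 of 64 at 24 h, 48 of 91 over both times and 96 of 117 for time. Fits to the libraries of 1 time, which called only 2 genes higher and 9 lower at 12 h, are not among these settings. Neither is the mean of the within-time contrasts, nor, for time, the replicate block within each time. The 0 at 24 h comes from the replicate block within each time, which called no gene there. The list calls of sarcomere genes passed in all 21 other settings in each EV comparison, as did those of NF-kB, cell cycle, cholesterol and ribosomal protein genes at 12 h, and those of excitation-contraction and glycolysis genes at 24 h. These 21 do not include camera with an estimated correlation, which called 0 lists in each EV comparison. Fewer settings kept the calls of NF-kB (12), TGF-beta (13), chemokines (16), histones (17), immediate early genes and oxidative phosphorylation (19 each) at 24 h, of mitochondrially encoded mRNAs (17) and chemokines (18) at 12 h, and of immediate early genes (16), cell cycle (17) and NF-kB (19) over both times. The calls of interferon and ribosomal protein genes at 24 h and of excitation-contraction and glycolysis genes at 12 h were kept in 20 of 21. The cause was not tested for any moved result unless stated. Where a left-out library leaves 1 in its group, that library is assumed to vary like the other groups.

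At 12 h the main counts were 479 higher and 1566 lower. They were 736 and 548 with median-ratio scaling, 754 and 541 after GC and length correction and 109 and 188 with array weights. Both control 12 h libraries had the same weight of 0.272, so the weights do not discount replicate 2 alone. Lower genes were 1017 with no filter, where more genes are tested, and 747 with quantile normalization. The 4 libraries of that time alone gave 2 and 9. The replicate block gave 291 and 823, the replicate block within each time 103 and 220, and the correction with the replicate block 351 lower. Leaving out each library gave 70 to 2183 higher and 142 to 3488 lower.

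At 24 h the main counts were 287 and 105. They were 167 and 58 with no filter, 719 and 449 with array weights and 491 and 272 from the 4 libraries of that time, and 185 were lower after GC and length correction. The replicate block gave 133 and 50, and the replicate block within each time 0 and 0. Leaving out each library gave 23 to 602 higher and 4 to 356 lower.

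Over both times the main counts were 461 and 477. They were 1078 and 1341 with array weights, and the mean of the within-time contrasts gave 1031 lower. The replicate block gave 286 lower, and the replicate block within each time 198 and 120. Leaving out each library gave 240 to 656 higher and 158 to 669 lower. For time, 1485 and 1008 in the main test, array weights gave 2824 higher, and leaving out each library gave 884 to 2523 higher and 640 to 1644 lower; the plan leaves out the replicate block within each time for counts of genes by time. With that block the time term compares the replicate 1 libraries alone, so it is not the time effect of the main test. For this term the higher share of the called genes was 58.7%, and of sarcomere genes 0 were higher and 6 lower. The main test over all libraries gave 59.6%, and 2 and 20. For sarcomere genes with MPC EVs, the replicate block within each time gave 6 higher at 12 h and 0 at 24 h. The replicate block gave 12 and 9. The count of genes with a different effect was 0 in the main test and in every setting that kept all 8 libraries, and 0 to 3668 when each library was left out.

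The main counts of called lists were 9 at 12 h, 11 at 24 h and 8 over both times. With an estimated correlation they were 0, 0 and 0. Fry called 15 at 12 h and 3 at 24 h. GC and length correction gave 14 at 12 h, also 14 with the replicate block. The filter at 5 FPKM, which leaves fewer genes and lists to test, gave 6 at 24 h and 5 over both times. Leaving out each library gave 8 to 11, 7 to 13 and 7 to 10. The correlation of the effects at both times was 0.23 in the main test, 0.42 after GC and length correction, alone or with the replicate block, and 0.76 over called genes, which are selected; leaving out each library gave 0.0308 to 0.546.

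Whether the replicate numbers pair the samples is not settled. Deviations of libraries with the same number in different groups correlated from -0.61 to 0.24. The value was 0.24 between the 24 h groups and -0.01 between the 12 h groups. The -0.61 was between control 12 h, which holds the library with the GC trend, and MPC EV 24 h. These values cannot exclude pairing within a time. At a depth of 16.3 to 20.2 M fragments, low and short genes rest on few fragments.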

Other observations

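Single genes of lists that camera did not call also changed. At 12 h the fatty acid gene Acsl1 and the coactivator gene Ppargc1a rose by 0.91 ± 0.08 and 1.01 ± 0.16 on the log2 scale, while Pdk4, a kinase that holds back pyruvate oxidation, fell by 0.93 (fatty acid handling: 2 of 20 higher, 2 lower; camera adjusted p = 0.437). Trim63, a ubiquitin ligase of muscle atrophy, went from 87.4 ± 9.60 to 45.7 ± 3.19 FPKM at 12 h, and 7 of 19 atrophy and proteolysis genes fell and 0 rose (adjusted p = 0.124). With median-ratio scaling, quantile normalization and GC and length correction 3, 5 and 3 were lower and 1, 1 and 0 higher; none of 19 passed at 24 h (adjusted p = 0.0508). Of p53 response genes 8 of 21 fell and 1 rose at 12 h (adjusted p = 0.295), and 5 were lower under each of these alternatives. Of oxidative and metal stress genes 5 of 20 fell and 1 rose (adjusted p = 0.321), but 1, 1 and 0 were lower and 2, 0 and 3 higher under these alternatives, so the direction of the counts turned in the first and the last. None of 23 unfolded protein response genes passed with MPC EVs at either time (camera adjusted p = 0.437 at 12 h and 0.465 at 24 h). Without control 12 h replicate 2 camera called that list as higher at 12 h, but not with an estimated correlation. Of 16 heat shock genes 1 rose at each time (adjusted p = 0.115 and 0.226). At 12 h 3, 5 and 5 of them were higher under the 3 alternatives, and of the unfolded protein response 1, 1 and 2. In the matrix list 2 of 31 rose and 5 fell at 12 h (adjusted p = 0.482), and 2 and 4 at 24 h (0.119). Among 21 remodelling enzymes and inhibitors 3 rose and 4 fell at 12 h (0.482), and 4 and 3 at 24 h (0.365). Of 22 components of vesicles and endosomes 3 fell at 12 h (0.777) and 1 rose at 24 h (0.94); at 12 h 1, 2 and 0 were lower and 1, 0 and 3 higher under the 3 alternatives.

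At 12 h the medians of the progenitor, fibroblast and pericyte lists were -0.29, -0.30 and -0.26, below that of all genes (-0.12), and at 24 h 0.04, 0.04 and -0.14. After GC and length correction the 12 h medians were -0.20, -0.05 and -0.03. Of 13 satellite cell and progenitor genes 2 rose and 5 fell at 12 h (adjusted p = 0.744; 3 higher and 3, 4 and 3 lower under the 3 alternatives), and 2 rose and 1 fell at 24 h (0.762). Of 8 fibroblast genes 2 fell at 12 h (0.594), and 1 rose and 1 fell at 24 h (0.741). Of 7 pericyte and smooth muscle genes 1 rose and 1 fell at each time (0.937 and 0.482). Lists with fewer than 5 tested genes had no list test: of 2 leukocyte genes Cd53 rose at 24 h by 0.99 ± 0.12, of 4 adipocyte genes Car3 fell by 1.2 at 24 h, and of 3 Schwann cell and neuron genes Erbb3 rose by 0.70 ± 0.11 and Tubb3 fell by 0.43 at 12 h. None of 2 nuclear retained RNAs and 1 endothelial gene passed, and 0 blood and liver genes were tested. The median, mean and test of a list differed in sign at 12 h for myogenic regulation (-0.08, 0.20, up), matrix (-0.05, -0.03, up), fatty acid handling (-0.05, 0.02, up) and the unfolded protein response (-0.01, 0.06, up), and at 24 h for fibroblasts (0.04, -0.16, down) and reported miR-1 and miR-206 targets (0.01, -0.04, up). Camera called none of these in the main test. Without control 12 h replicate 2 it called myogenic regulation and the unfolded protein response at 12 h.

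Other splits of the 8 libraries into 4 and 4 were fitted with the same terms. For MPC EVs over both times 1 of 34 splits, the real one with 938 genes, gave as many, and the highest other gave 1. The smallest share that this count can reach is 1 of 34, and most other splits separate libraries of the same group. It therefore argues against chance only if the libraries are independent, which the labels do not say. For time 1 of 34 gave as many, the real one with 2493 genes, and the highest other gave 0, with the same limits. If the 2 libraries of a group come from 1 culture, neither count excludes a difference between cultures. The split equal to the other factor could not be fitted.

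A hypothesis that MPC EVs oppose the change between 12 h and 24 h was tested with effects taken from different replicates, so that no library entered both. Across genes r was -0.14 and -0.34 after GC and length correction and -0.18 and -0.43 as deposited, which is in line with it. A reference contrast, the difference of the EV effects against time, gave -0.20 and 0.25 after the correction. The -0.14 lies within these values and the -0.34 lies below both. Whether the reference is unrelated to time was not tested, and so few values do not decide the question.

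A hypothesis of more miR-206 activity in the treated myotubes was tested on genes with the seed site ACATTCC in the 3' UTR (1183 of 10354). Their log2 fold change over both times differed from that of other genes by -0.02 (-0.0165), and 15 of 210 shuffled sites, the real one included, gave a value as low (7.14%). At 12 h the difference was -0.03 (rank 10 of 210) and at 24 h -0.00 (rank 70). After GC and length correction the rank was 16 at 12 h, 66 at 24 h and 23 over both times. A term for the spread of shuffled sites was added to this test after the first values were seen. By the rule set in advance, the rank over both times counts against the hypothesis. With the added term the test leaves it undecided.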
